A study of Homo sapiens with 4 samples.

How the data were processed

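MicroRNAs were measured by quantitative reverse-transcription PCR on TaqMan array cards in RPMI8226, an established human multiple myeloma cell line. There were 4 samples, 1 per group: cells and the exosome fraction of their culture medium, each after 24 h at 20% or 1% oxygen. Exosomes are small vesicles that cells release. Per the labels' protocols, the exosome fraction came from 5 ml of medium that was cleared by centrifugation, filtered and precipitated with a polymer reagent, a method that enriches vesicles without separating them from everything else in the medium. A synthetic plant miRNA, ath-miR159, was added at lysis as a spike-in (1 µl at 1 nM), and 3 µl of each 50 µl RNA eluate went into reverse transcription. Per the labels' protocols, only the exosome products were then pre-amplified.

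The authors' first deposited table holds the threshold cycle (Ct) of each well, not normalized: the PCR cycle at which fluorescence crosses a threshold, so that 1 cycle less stands for a doubling of template at full efficiency. Its 384 wells comprise 377 assays of human miRNAs with 1 well each, 4 wells of the small nuclear RNA U6, and 1 well each of RNU44, RNU48 and ath-miR159. The highest Ct in the table is 35, and a large share of wells holds exactly that value. It was therefore read as a ceiling that means not detected, although how it was set is not given in the sources used here. The second deposited table gives the authors' fold (the ratio of hypoxia over normoxia) per well, and per the series' design text a U6 small RNA was the invariant control for the cells and the spike-in that for the exosome fraction, with Data Assist software version 3.1. Ratios recomputed from the Ct values differed from the authors' deposited ratios by at most 0.000356 on the log2 scale among miRNAs detected in both samples of a comparison, with the mean of the U6 wells on the card and the spike-in as normalizers, which settles the direction and the normalizers of that table. The authors' table also gives a ratio to wells at the ceiling, as if 35 had been measured: 207 assays at the ceiling in both cell samples have the ratio 0.9965, and 140 at the ceiling in both exosome samples have 1.0376. These are not used as measurements here. A single Ct per well carries no depth or count, so no counting interval applies to an expression value. The precision is limited by 1 sample per group and 1 well per miRNA.

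Log2 changes were computed as the negative difference in normalized Ct between hypoxia and normoxia, with the mean of the U6 wells as normalizer in cells and the spike-in in the exosome fraction. An assay entered a count of changes when its Ct was under 35 in both samples, and 2-fold was the threshold. A miRNA at the ceiling in only 1 of the samples has a bound, computed against Ct 35 and written as "at least". The response of the exosome fraction was set against that of the cells by the difference of the log2 changes, over assays under Ct 35 in all 4 samples. Exosome fraction and cells were compared after subtracting each sample's median Ct over those assays, and an assay was counted at 4-fold or more in the same direction in both oxygen conditions. No test between groups was made, because each group is 1 sample, and no p-value is given. A fit of oxygen and compartment over all 4 samples would have to take the difference in response between the compartments, itself one of the comparisons, as its error. Separate cultures, if any, behind a sample are not stated in the labels.

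A total of 15 miRNA lists (families, genomic clusters, hypoxia and vessel-related sets) and 8 lists of miRNAs typical of particular cell types were fixed before the data were examined. For each list, the median log2 change was placed among 10000 random lists of the same size drawn within 5 bins of mean Ct, as a description of these samples only. Named miRNAs followed a rule fixed at the same time. It takes the control assays, miR-210 and miR-135b, the 10 highest and 10 lowest log2 changes per oxygen comparison among assays under Ct 32 in at least 1 sample and under 35 in both, and up to 5 per direction that were under Ct 32 in 1 sample and at the ceiling in the other. It also takes the 5 largest per direction for the other comparisons and the members of each list with the lowest mean Ct. Members of a list that are named because they were past 2-fold, or seen in only 1 of the samples, were chosen after their values were seen unless the rule holds them, as was any other miRNA marked so. Passenger strands were left out of the lists. No genome build belongs to the assays, so no coordinates are given, and a RefSeq gene table (assembly GRCh38.p14) was used only to find which miRNA genes are neighbours; 346 of the 377 assays matched a gene there.

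The calculation was tested on simulated data made from the measured Ct values with noise of the size seen between U6 wells. All 40 miRNAs changed 4-fold were recovered in each simulation, of 147 assays for cells and 203 for the exosome fraction, and no unchanged assay was called. That noise (SD 0.137 cycles) is of abundant wells and leaves out differences between cultures. Against it, changes of 4-fold lie far from the 2-fold threshold, so recovery was nearly certain beforehand. The simulated controls also had no noise of their own between samples. The simulation therefore checks the arithmetic and its direction, not the reliability of calls near 2-fold or at high Ct. Alternatives were other normalizers, each U6 well left out, detection limits, fold thresholds and the authors' deposited ratios. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.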

Results

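The levels of 377 human miRNAs were measured in RPMI8226 myeloma cells and in the exosome fraction of their medium after 24 h at 20% oxygen (normoxia) or 1% oxygen (hypoxia), with 1 sample in each of the 4 groups. A Ct under 35 was recorded for 162 miRNAs in normoxic cells, 155 in hypoxic cells, 221 in the normoxic exosome fraction and 219 in the hypoxic exosome fraction. The median Ct of the detected miRNAs was 31.12 and 30.99 in the cell samples and 27.0 in both exosome samples, which had been pre-amplified. In 3 of the 4 samples the lowest Ct among miRNAs belonged to miR-19b, a member of the miR-17-92 cluster that is active in many blood cancers. It stood at 21.0 in hypoxic cells, 14.3 in the normoxic and 15.0 in the hypoxic exosome fraction. In normoxic cells miR-493 was lower still, at 20.9. No value between groups has a replicate error, because each group is a single sample.

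The control RNAs differed little between the oxygen conditions. U6, a small nuclear RNA of the splicing machinery, had a Ct of 18.82 ± 0.15 in normoxic cells and 18.81 ± 0.12 in hypoxic cells (SD, n = 4 wells of 1 sample). The small nucleolar RNAs RNU44 and RNU48, normalized to U6, were 1.22-fold and 1.01-fold in hypoxic over normoxic cells. All 3 of these RNAs stood at the ceiling in both exosome samples. The spike-in ath-miR159 had a Ct of 22.94 in the normoxic and 22.99 in the hypoxic exosome fraction, and stood at the ceiling in both cell samples. The spread between U6 wells is the only repeat measurement in the data, and it describes an abundant RNA within 1 card.

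The first comparison asked which cellular miRNAs differ under hypoxia. miR-210, the miRNA best known to be induced by hypoxia-inducible factor, was 11.7-fold higher in hypoxic cells (Ct 30.998 in normoxia and 27.441 in hypoxia). This was the largest difference among the 147 miRNAs detected in both cell samples. Of these, 11 were at least 2-fold higher in hypoxia, 9 at least 2-fold lower, and 127 within 2-fold. The median log2 change was 0.03, and the middle 95% of miRNAs lay between -1.19 and 1.31. Of these, 5 of the 11 higher and 5 of the 9 lower miRNAs had a Ct under 32 in at least 1 sample, and with Ct under 32 required in both samples the counts were 1 and 4. With RNU44 and RNU48 as normalizers, which moved every cellular log2 change by -0.15, the counts were 6 higher and 10 lower.

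After miR-210, the higher miRNAs with a Ct under 32 in at least 1 cell sample lay close to the 2-fold line. miR-130b was 2.45-fold, miR-491-5p 2.33-fold, miR-423-5p 2.11-fold and miR-328 2.08-fold higher in hypoxia. The ratios of miR-423-5p and miR-328 rest on steps of about 1 cycle between Ct values within 0.1 of a whole cycle, and were below 2-fold with RNU44 and RNU48 as normalizers (0.93 and 0.91 on the log2 scale). Below 2-fold were miR-184 (1.93-fold), miR-494 (1.88-fold), miR-324-5p (1.84-fold), miR-150 (1.82-fold), a lymphocyte miRNA, and miR-365 (1.66-fold). Among the lower miRNAs with a Ct under 32 in at least 1 cell sample, miR-197 was 2.40-fold, miR-520e 2.31-fold, miR-28-3p 2.18-fold, miR-19a 2.13-fold and miR-221 2.04-fold lower in hypoxia. miR-221, a known repressor of the cell-cycle inhibitor CDKN1B, also differed by such a step, and was within 2-fold with the median normalizer and without 1 of the U6 wells (-0.97 on the log2 scale). The next were miR-23a (1.66-fold), miR-183 (1.49-fold), miR-330-3p (1.48-fold), miR-886-3p (1.48-fold) and miR-628-5p (1.47-fold). At a Ct above 32 in both samples, larger ratios than those of miR-130b and miR-197 were found for miR-194 (4.36-fold), miR-193a-3p (3.00-fold) and miR-32 (2.54-fold), which were higher, and for miR-422a (4.31-fold) and miR-429 (2.76-fold), which were lower; miR-32 was named after its values were seen. A further 15 miRNAs were detected in normoxic cells only and 8 in hypoxic cells only, most of them with a Ct above 32. With a Ct under 32 there were 3, all seen in normoxia only: miR-493 was at least 17199-fold, miR-15a at least 30.0-fold and miR-449a at least 24.1-fold lower in hypoxia, each from 1 well per sample.

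**Figure D1:**
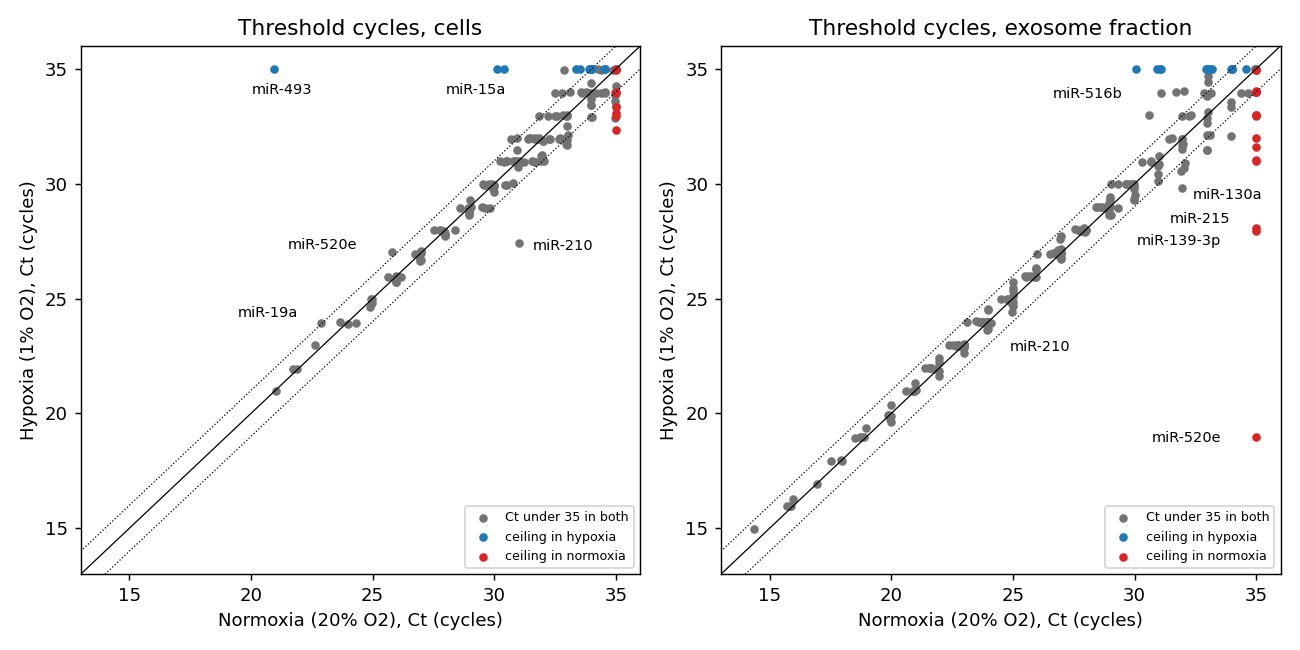
Threshold cycles (Ct, in cycles) of each human miRNA at 20% oxygen (x axis) against 1% oxygen (y axis), in cells on the left and in the exosome fraction on the right; each point is 1 well, a lower Ct means more template, the solid line marks equal Ct and the dotted lines a difference of 1 cycle. miR-210 lies well below the line in cells (30.998 and 27.441) and near it in the exosome fraction (24.0 and 23.7), and the coloured points are miRNAs at the ceiling of 35 in 1 sample.

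Of the 158 members that the 15 fixed lists hold, counting a miRNA once in each list it belongs to, 74 were measured in both cell samples and 67 of these lay within 2-fold. In the list of 15 hypoxia reference assays, 14 were detected in both samples, and only miR-210 was past 2-fold. The list's median log2 change was 0.19, at percentile 89.1 of matched random lists. Its members with the lowest mean Ct over all 4 samples were miR-24 (0.08), miR-26a (0.23), miR-21 (-0.24) and miR-27a (0.17). miR-107 was seen in hypoxic cells only, at Ct 33.1. The list tied to vessel formation and hypoxia-inducible factor had 13 measured assays and a median of 0.01, at percentile 43.6. In it, miR-135b, which has been linked to factor-inhibiting HIF, was 1.15-fold in hypoxic over normoxic cells, at Ct 34.0 and 34.2. The miR-17 family clusters had 12 measured members and a median of -0.15, at percentile 2.78. Within these clusters miR-19a was the only member past 2-fold, while miR-19b (0.03), miR-17 (-0.07), miR-106a (-0.22) and miR-20a (-0.34) lay within it.

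Of the other families, the 8 let-7 assays had a median log2 change of 0.06 at percentile 48.2, with let-7e at 0.19, let-7b at -0.46 and let-7g at 0.19. miR-98 was the only member past 2-fold, at Ct 34.97 and 33.88, and was below it with RNU44 and RNU48 as normalizers (0.94). The miR-29 family had a median of 0.38 at percentile 92.9 (miR-29a 0.38, miR-29c 0.13). The group of miR-99, miR-100 and miR-125 had a median of 0.39 at percentile 91.6 (miR-125b 0.07, miR-100 0.51, miR-99a 0.67). The miR-15/16 family had 3 measured members and a median of -0.31 at percentile 6.76 (miR-16 -0.31, miR-15b -0.47), with miR-15a seen in normoxia only and miR-424 in hypoxia only. The miR-200 family, typical of epithelial cells, had a median of -0.14 at percentile 24.9 (miR-200b 0.32, miR-200a -0.10, miR-429 -1.47). The small lists gave medians of 0.05 for miR-30 (miR-30c 0.01, miR-30b 0.09), -0.24 for miR-181 (miR-181a 0.23, miR-181c -0.72) and -0.37 for miR-221 and miR-222 (miR-222 0.29, miR-221 -1.03). Of the miR-183 cluster only miR-183 (-0.57) and of the miR-371 cluster only miR-373 (0.45) were measured. The large imprinted DLK1-DIO3 cluster was mostly not detected in cells, with 35 of its 39 assays at the ceiling in both cell samples. Its median was 0.16 over 3 measured (miR-494 0.91, miR-323-3p -0.73). In the placental cluster C19MC, 32 of 35 assays were at the ceiling in both, and only miR-520e was measured in both.

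Of the markers of blood and lymphoid cells, 7 of 10 assays were measured in cells, with a median log2 change of -0.02 at percentile 30.4. miR-146a (0.23), miR-142-3p (-0.02) and miR-150 (0.86) had the lowest mean Ct over all 4 samples. The epithelial list had 6 of 8 measured and a median of -0.14 at percentile 21.6 (miR-203 0.71, miR-205 -0.88). The nervous system list had 3 of 10 measured, with a median of 0.06 at percentile 54.2 (miR-138 0.23, miR-9 0.06). The endothelial list had 2 measured (miR-126 0.01, miR-139-5p -0.32), and the red cell list only miR-126. Of the fibroblast list only miR-199a-3p (-0.48) was measured. No muscle assay was measured in both samples; miR-133a was seen in hypoxia only and miR-1 in neither. The liver list had a median of 1.36 at percentile 98.3 from miR-194 (2.13) and miR-192 (0.59), both with Ct values from 32.84 to 34.97. Of the 22 lists with a measured assay, this one and C19MC had a percentile outside the middle 95% of random lists, against 1.1 expected by chance. C19MC rests on miR-520e alone (percentile 1.66), and its value equalled the lower limit of the random lists (-1.21). With miRNAs seen in only 1 sample at their bounds, the cellular medians were -0.51 for C19MC, -0.28 for DLK1-DIO3 and -0.16 for the nervous system list.

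The second comparison asked which miRNAs differ in the exosome fraction when the cells are hypoxic. miR-210 was 1.31-fold higher in the hypoxic exosome fraction (Ct 24.0 in normoxia and 23.7 in hypoxia), and miR-135b was 1.04-fold (Ct 30.0 in both). Of the 203 miRNAs detected in both samples, 8 were at least 2-fold higher, 7 at least 2-fold lower and 188 within 2-fold. The median log2 change was -0.07, and the middle 95% lay between -1.36 and 1.36. Each of the 15 miRNAs past 2-fold had a Ct of 29.8 or more in both samples, and with Ct under 32 required in both the counts were 2 higher and 0 lower. Each sample's median Ct over the miRNAs as normalizer moved every log2 change by 0.20 and gave 10 higher and 6 lower. This did not centre the log2 changes at 0, because their median before the shift was -0.07.

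The highest ratio among the 203 was that of miR-130a, a miRNA known to promote an angiogenic endothelial phenotype, which was 4.54-fold higher (Ct 31.96 and 29.83). It was followed by miR-448 (3.87-fold higher), at a Ct above 32 in both samples and named after its value was seen. Among the other miRNAs with a Ct under 32 in at least 1 sample, miR-202 and miR-224 were each 2.92-fold higher, miR-338-3p 2.65-fold, miR-33b 2.59-fold and miR-323-3p 2.30-fold. miR-141 (1.88-fold), miR-449b (1.65-fold), miR-219-1-3p (1.60-fold) and miR-183 (1.56-fold) followed below the threshold. The lower miRNAs under the same Ct limit were led by miR-516b (7.10-fold), miR-489 (5.05-fold) and miR-548d-3p (4.68-fold). Of those named as past 2-fold, miR-323-3p, miR-448 and miR-516b had Ct values within 0.1 of a whole cycle in both samples. Within 2-fold were miR-190 (1.89-fold lower), miR-9 (1.87-fold), miR-331-5p (1.86-fold), miR-181a (1.73-fold), miR-301b (1.65-fold), miR-532-3p (1.56-fold) and miR-628-5p (1.54-fold). There were 18 miRNAs detected in the normoxic exosome fraction only and 16 in the hypoxic one only. Those seen with a Ct under 32 in hypoxia only were led by miR-520e, at least 68808-fold higher, then miR-139-3p (at least 138-fold), miR-215 (at least 127-fold), miR-129-5p (at least 16.6-fold) and miR-187 (at least 16.3-fold). Those in normoxia only were miR-509-5p (at least 29.2-fold lower in hypoxia), miR-146b-3p (at least 16.2-fold), miR-296-3p (at least 14.9-fold) and miR-133b (at least 14.6-fold). Each of these bounds rests on 1 well per sample.

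In the exosome fraction 81 of the 158 list members were measured in both samples, and 78 of these lay within 2-fold. The hypoxia reference list had 12 measured assays, none past 2-fold, and a median log2 change of -0.15 at percentile 29.1 (miR-24 -0.25, miR-26a -0.52, miR-21 0.26). The vessel-related list had a median of -0.10 at percentile 47.6, with miR-130a past 2-fold. The miR-17 family clusters had a median of -0.13 at percentile 53.7 (miR-19b -0.57, miR-17 -0.08, miR-19a 0.44). The let-7 family had 5 measured members and a median of -0.29 at percentile 8.34 (let-7e -0.55, let-7g -0.45, let-7b -0.29). The miR-15/16 family had a median of -0.04 at percentile 63.9 (miR-16 0.11, miR-15b 0.41), miR-29 0.12 at percentile 92.5 (miR-29a 0.02, miR-29c 0.39) and miR-30 -0.18 at percentile 42.5 (miR-30b -0.33, miR-30c -0.02). The group of miR-99, miR-100 and miR-125 had a median of 0.15 at percentile 94.4 (miR-100 0.19, miR-125b -0.35), which became -0.03 with miR-125a-3p, seen in normoxia only, at its bound. miR-221 and miR-222 gave -0.25 (miR-222 -0.37, miR-221 -0.14) and the miR-200 family 0.11 at percentile 89.6 (miR-200b -0.16, miR-200a 0.38). The miR-371 cluster was measured through miR-373 (-0.34) alone. The DLK1-DIO3 cluster had 5 measured assays and a median of 0.20 at percentile 49.4, with 3 assays seen in normoxia only and 4 in hypoxia only.

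Of 23 lists, 4 had a percentile outside the middle 95% of random lists in the exosome fraction, against 1.15 expected by chance. Among the 4, the miR-181 family and the miR-183 cluster only equalled a limit of that range. C19MC had 8 measured assays and a median log2 change of -0.39 at percentile 1.78 (miR-518b -0.47, miR-517a -0.31, miR-519a -0.61). Of these only miR-516b was past 2-fold, and 4 further members were seen in normoxia only and 2 in hypoxia only. The nervous system list had a median of 0.19 at percentile 98.2 over 6 assays, none of them past 2-fold (miR-138 0.02, miR-9 -0.90, miR-128 -0.33, miR-219-5p 0.36). The miR-181 family (miR-181a -0.79, miR-181c -0.27) and the miR-183 cluster (miR-183 0.64) were counted with 2 assays and 1 assay. Their medians equalled the lower limit (-0.53) and the upper limit (0.64) of the random lists. They were counted because ties enter a percentile only in part. With miR-96, seen in normoxia only, at its bound the median of the miR-183 cluster was 0.13. Blood and lymphoid markers had 8 of 10 measured and a median of -0.06 at percentile 60.6 (miR-146a -0.16, miR-142-3p -0.40). The epithelial list had 0.04 at percentile 84.5 (miR-203 0.04, miR-205 0.04), the liver list -0.08 at percentile 65.5 (miR-194 -0.11, miR-192 -0.05) and the endothelial list 0.01 at percentile 70.2 (miR-126 -0.27, miR-139-5p 0.29). The muscle list had 0.46 at percentile 77.3, which became -0.51 with miR-133b and miR-499-5p, seen in normoxia only, at their bounds (miR-133a -0.08, miR-1 1.00). The fibroblast list was measured through miR-199a-3p (0.05). Of the red cell and platelet list, miR-126, which the endothelial list also holds, was at Ct 21.6 and 21.97 in the exosome fraction. miR-451 was seen in normoxia only, at Ct 33.2, and both miR-486 assays stood at the ceiling in all 4 samples. With miRNAs seen in only 1 sample at their bounds, the medians were -0.16 for the blood, -1.01 for the red cell, 0.29 for the endothelial, 0.36 for the nervous system and 0.55 for the fibroblast list, 0.32 for DLK1-DIO3 and -0.12 for the miR-371 cluster.

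The third comparison set the response of the exosome fraction against that of the cells. Among miRNAs detected in all 4 samples miR-210 differed most: its log2 change was 3.55 in cells and 0.39 in the exosome fraction, a difference of -3.16. Of these 138 miRNAs, 8 had a response at least 2-fold higher in the exosome fraction than in cells and 14 at least 2-fold lower. With each sample's median Ct as normalizer in both compartments these counts were 13 and 10, and with Ct under 32 in all 4 samples 2 and 5. None was at least 2-fold higher in both compartments and none at least 2-fold lower in both. Such an overlap could hardly occur, because only miR-323-3p among these 138 was past 2-fold in the exosome fraction. Across these miRNAs the responses had a Pearson correlation of 0.01 and a Spearman correlation of 0.00, and the Pearson correlation was -0.06 without miR-210. Assays are not independent replicates, and the correlation describes these samples only. After miR-210, the responses most below those of the cells were miR-194 (difference -2.24), miR-193a-3p (-1.85), miR-301b (-1.77) and miR-491-5p (-1.53). Those most above were miR-323-3p (1.93), miR-449b (1.74), miR-422a (1.60), miR-19a (1.53) and miR-429 (1.21). Of these, miR-19a alone had a Ct under 24 in all 4 samples, and its change in cells was a step of about 1 cycle (log2 -1.09). The others had a Ct above 32 in at least 1 cell sample. For miR-135b the difference was -0.14.

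**Figure D2:**
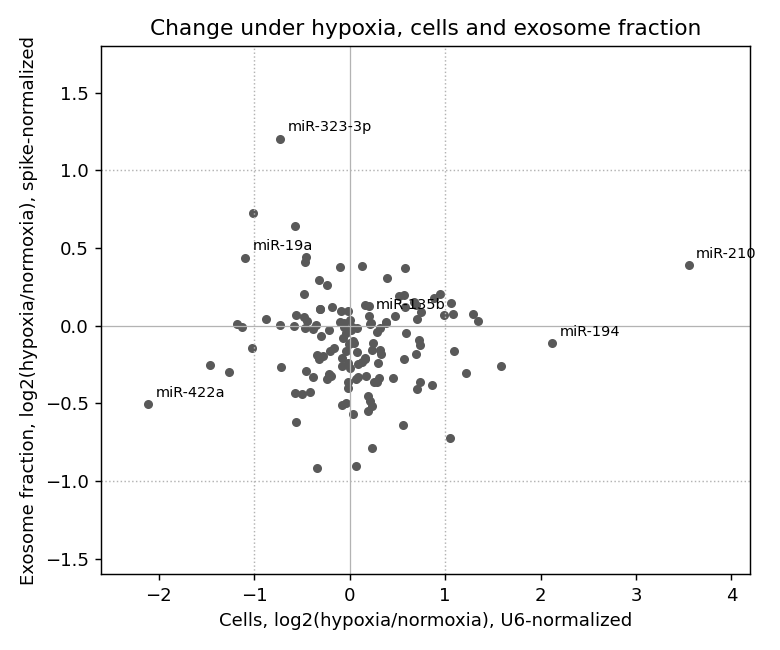
Log2 ratio of hypoxia over normoxia in cells (x axis, normalized to U6) against that in the exosome fraction (y axis, normalized to the spike-in) for the 138 miRNAs with a Ct under 35 in all 4 samples; each point is 1 miRNA and the dotted lines mark 2-fold. miR-210 lies at 3.55 in cells and 0.39 in the exosome fraction, and no point is past 2-fold in the same direction on both axes. Only miR-323-3p is past 2-fold in the exosome fraction.

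The last comparison described how the miRNA content of the exosome fraction differed from that of the cells. The Ct values of the 138 miRNAs correlated across assays between cells and exosome fraction, with a Pearson correlation of 0.87 in each oxygen condition. After centring each sample on its median, 4 miRNAs were at least 4-fold higher in the exosome fraction in both oxygen conditions and 23 at least 4-fold lower, or 5 and 9 with Ct under 32 in all 4 samples. The higher ones were miR-373 (16.3-fold as the mean of both conditions), miR-20b (7.71-fold), miR-361-5p (5.57-fold) and miR-92a (4.17-fold). The lower ones were led by miR-454 (76.7-fold), miR-190 (49.6-fold), miR-362-5p (27.7-fold), miR-422a (26.7-fold) and miR-125a-5p (25.2-fold). The centred differences in normoxia and hypoxia had a Pearson correlation of 0.91 across assays. A set of 50 miRNAs was detected in both exosome samples and in neither cell sample, and 33 of these had a Ct under 32. Conversely, 7 miRNAs were detected in both cell samples and in neither exosome sample: miR-103, let-7a, let-7f, miR-487a, miR-200c, miR-23b and miR-98, all of that set, named after their values were seen. Neither set could enter the counts of 4 and 23, which needed a Ct under 35 in all 4 samples. The median Ct of the 138 miRNAs lay closer to the ceiling in cells (30.91 and 30.97) than in the exosome fraction (23.96 and 23.99). miRNAs higher in the exosome fraction were thus cut off more easily, so 4 against 23 does not show which direction prevailed. miR-22, named after its values were seen, was at the ceiling in cells and at Ct 25.01 and 25.12 in the exosome fraction. Only the exosome products were pre-amplified, so that differences between assays in pre-amplification enter each value of this comparison.

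In all 4 samples the Ct values were not spread evenly between whole cycles. The final 0.1 cycle before a whole number held 45.8% of the wells under the ceiling in normoxic cells (95% exact Clopper-Pearson interval 38.1% to 53.7%) and 65.8% in hypoxic cells (58.0% to 73.1%). It held 51.8% in the normoxic (45.0% to 58.5%) and 59.5% in the hypoxic exosome fraction (52.7% to 66.1%), where an even spread would give 10%. The intervals treat wells as independent. For such wells a difference between samples falls near 0 or near a whole number of cycles. Of the 147 miRNAs measured in cells 11 had an absolute log2 change between 0.9 and 1.1, and of the 203 in the exosome fraction 6 did. Neighbouring bands were not counted, so these counts do not show an excess near 1 cycle.

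**Figure D3:**
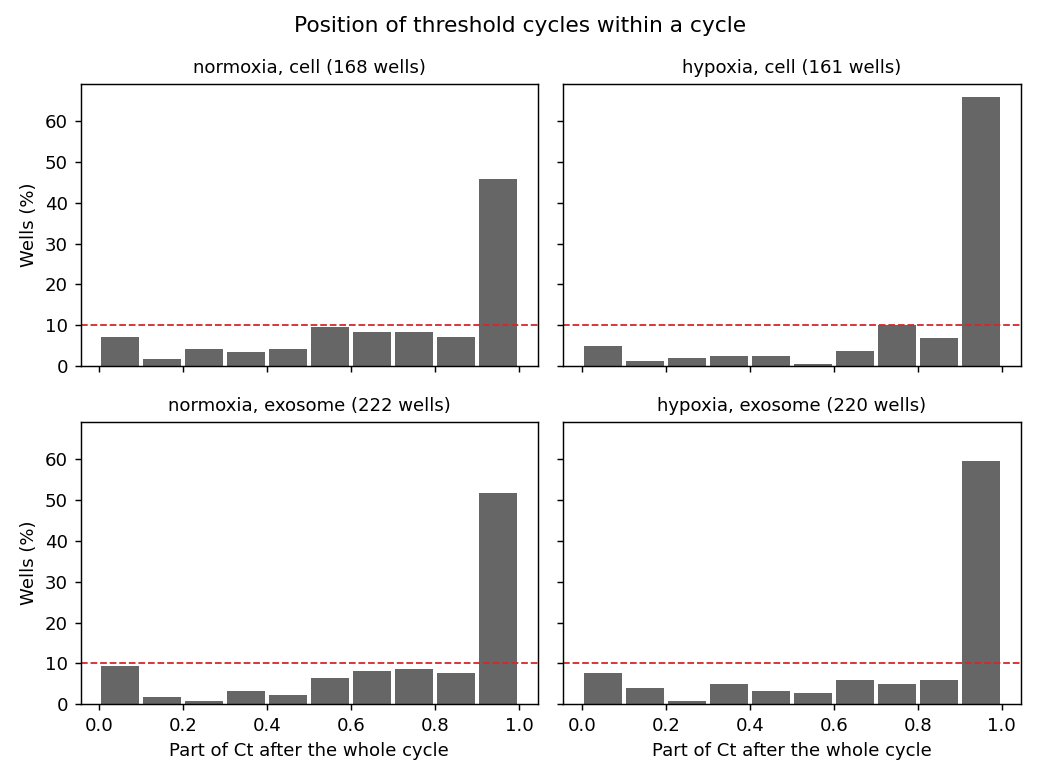
Share of wells (y axis, percent of wells with a Ct under 35) by the part of the Ct after the whole cycle (x axis, in steps of 0.1 cycle) in each sample; the dashed line marks the 10% of an even spread. The final 0.1 cycle holds between 45.8% and 65.8% of the wells in every sample.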

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

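The tests on C19MC and DLK1-DIO3 in this part were chosen only after the values were seen. miR-520e was the only miRNA at least 2-fold in opposite directions in cells and exosome fraction, bounds included. It was 2.31-fold lower in hypoxic cells (Ct 25.8 and 27.0) and at least 68808-fold higher in the hypoxic exosome fraction (ceiling in normoxia, Ct 18.98 in hypoxia), a difference of at least 17.28 on the log2 scale. With 1 sample per group the difference was not tested. miR-493 is a similar case in the opposite direction: Ct 20.9 in normoxic cells, the lowest of any miRNA there, and the ceiling in the other 3 samples. A rise of the whole C19MC cluster is argued against for miR-520e: the 12 other members seen in the normoxic exosome fraction, with the 4 at the ceiling in hypoxia taken at their bounds, had a median log2 change of -0.54 and a highest value of 0.91, although miR-519c-3p, at the ceiling in normoxia, was at least 2.11-fold higher. A fall of the whole DLK1-DIO3 cluster stays open for miR-493, although no other member was seen to go to the ceiling with it. The 3 other members seen in normoxic cells were seen in hypoxia too. Their log2 changes ran from -0.73 to 0.91, with a median of 0.16. A fall as large as that of miR-493 would have put them at the ceiling. They lay only 0.73 to 3.08 cycles from it, with 1 well each per sample, which is too little to decide. A failed or spurious single well cannot be told apart from a change of that miRNA alone, because the card holds 1 well per assay.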

How the results depend on the processing

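The fold thresholds of 1.9 and 2.5 and the removal of wells near a whole cycle were chosen after seeing the data; all other settings were fixed before. The log2 change of miR-210 in cells was 3.40 to 3.61 under each normalizer tried (U6, RNU44 with RNU48, median of miRNAs), with each U6 well left out and in the authors' deposited ratios. In cells the 11 higher and 9 lower miRNAs became 6 higher and 10 lower with RNU44 and RNU48 as normalizers, which moved all values by -0.15, 1 higher and 4 lower with Ct under 32 in both samples, 17 and 21 with the ceiling taken as measured, 28 higher at 1.5-fold, and 4 and 2 at 2.5-fold. In the exosome fraction the 8 higher and 7 lower became 2 and 0 with Ct under 32 in both samples, 22 and 18 with the ceiling taken as measured, and 15 and 20 at 1.5-fold. A stricter limit removes wells by construction, so most miRNAs past 2-fold have a Ct of 32 or more in at least 1 sample. The responses that differed between the compartments were 8 higher and 14 lower in the exosome fraction. They became 13 and 10 with each sample's median Ct as normalizer, and 2 and 5 with Ct under 32. The 23 miRNAs lower in the exosome fraction than in cells became 9 with Ct under 32, and the 162 detected in normoxic cells became 99. Of the exosome lists, 2 in place of 4 had a percentile outside the middle 95% of random lists with Ct under 32. Leaving out each U6 well gave 11 to 13 higher and 7 to 9 lower in cells. Counts under the other settings were within 1.5 times of those reported. Over the named miRNAs and lists, 277 alternative values were computed, of which 71 moved by more than 0.137 cycles, the SD between U6 wells. The shifts of -0.15 and 0.20 alone put every value under those normalizers past that limit. No named miRNA past 2-fold changed sign, but 14 of 86 list medians did. For the named miRNAs this was fixed beforehand, because a normalizer moves all values of a comparison alike, here by at most 0.20. In the exosome fraction the median Ct as normalizer moved all values by 0.20. That turned the hypoxia reference list to 0.04, the vessel-related list to 0.10, miR-17 to 0.07, miR-15/16 to 0.16, miR-30 to 0.02, blood to 0.14 and liver to 0.12. The median log2 change there had been -0.07, so the shift went past a centring at 0. These sign changes therefore depend on that choice of normalizer. A Ct under 32 turned the cellular medians of miR-181 to 0.23, the miR-200 family to 0.11 and the epithelial list to 0.32, and exosome muscle to -0.08; the other 3 lay within 0.137 of their main value. The spike-in in cells, and U6 in the exosome fraction, could not be used as normalizers because they stood at the ceiling, and a detection limit above the ceiling was not run because the highest Ct is 35. No replicates could be paired between the oxygen conditions, because each group holds 1 sample.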

Other observations

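Of the tests in this part, those on the level in the cells, the level of template and neighbouring miRNAs were set before their results were seen; the others were chosen after, as was the set of miRNAs counted for the level in the cells. The related miRNAs miR-192, miR-194 and miR-215 had higher values in hypoxic cells, with log2 changes of 0.59 and 2.13 for the first pair and miR-215 seen in hypoxia only, but at Ct values of 32.8 to the ceiling. In the exosome fraction miR-192 and miR-194 were measured near Ct 27 with log2 changes of -0.05 and -0.11, while miR-215 was at the ceiling in normoxia and at Ct 28.1 in hypoxia. These miRNAs were picked after their values were seen. The members of 1 cluster also parted in cells: miR-19a was 2.13-fold lower at Ct 22.9 and 24.0, while miR-19b, which shares a primary transcript with it but has another gene copy elsewhere, had a log2 change of 0.03. The change of miR-19a was a step of about 1 cycle, and its hypoxic Ct lay in the final 0.1 before a whole cycle. It may therefore share the limit of the other such steps.

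Threshold cycles piled just below whole cycles in all 4 samples. Pre-amplification as the cause is argued against by the cell samples, which were not pre-amplified and had 45.8% or more of their wells in the final 0.1 cycle (95% exact Clopper-Pearson interval of the lower sample 38.1% to 53.7%). Sampling noise of low template predicted a larger share at high Ct. Over all 4 samples together the share was 59.8% at Ct under 28 and 50.2% at Ct 31 or more, a difference of -9.63 percentage points. The pile was thus not confined to high Ct. The pooled shares cannot decide about low template, because only the exosome products were pre-amplified and the cell wells were not split by Ct. A low Ct in the exosome fraction need not mean much template before that step. In hypoxic cells, without that step, miR-19b, miR-17 and miR-20a lay in the final 0.1 cycle at low Ct (20.98, 21.95 and 22.96). The same miRNAs did not in normoxic cells (21.02, 21.88 and 22.63). A step of the cycle calling shared by all wells remains a candidate explanation, since all 4 samples show the pile, but without amplification curves it cannot be told apart from other causes. Of the 8 U6 wells in cells, 2 lay in the final 0.1 cycle.

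The 7 miRNAs seen in both cell samples and in neither exosome sample included miR-103, at Ct 29.1 and 28.99 in cells, and let-7a and let-7f were at the ceiling while let-7b, let-7c and let-7e had Ct values of 21.6 to 24.0 there. A low level in the cells is argued against as the whole cause: of all miRNAs seen in both cell samples within the cell Ct range of miR-103, let-7a and let-7f (29.0 to 31.6), these included, 37 of 41 were seen in both exosome samples, or 90.2% (exact interval 76.9% to 97.3%). In the range of miR-487a, miR-200c, miR-23b and miR-98 (31.9 to 34.4) it was 40 of 44, or 90.9% (78.33% to 97.47%), and 45 of 52, or 86.5% (74.2% to 94.4%), with miRNAs seen in only 1 cell sample. Assays that fail in the pre-amplified reactions and retention of these miRNAs in the cells both predict all 7 at the ceiling in both exosome samples and cannot be told apart, because no cell sample was pre-amplified.

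Whether the changes hold shared regulation was asked from neighbouring miRNA genes (within 10 kb). All matched miRNAs detected in both samples entered, those past 2-fold included. In cells, 61 neighbouring pairs had a mean absolute difference in log2 change of 0.52, against a mean of 0.72 when assays were shuffled, at percentile 3.44 of 10000 shuffles. In the exosome fraction 86 pairs had 0.41 against 0.56, at percentile 6.83. Both missed the limit of 2.5 set beforehand, and the percentiles were 16.9 and 16.5 when assays were shuffled within 5 bins of mean Ct, a match that the first shuffles lacked. The limit had been written to count any higher percentile against the hypothesis, and by that rule both comparisons count against it. Percentiles from 3.44 to 16.9 nevertheless lie on the predicted side of the shuffled means. They neither show shared changes nor exclude them, and the question stays open.

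The spike-in was at the ceiling in both cell samples, although per the labels' protocols it was added to every lysate.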
